A study of Mus musculus with 168 samples.

How the data were processed

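Single cells were profiled by Smart-seq2 in SVZ (133 cells), striatum (13 cells) and somatosensory cortex (4 cells) of old mice. Cells were picked by hand after sorting and each has 1 column of values. The deposited values are TPM, as read from their range, decimals and column sums. The submitters' notes name STAR 2.4.0g1, RSEM 1.2.18 and the build mm10 but give no gene annotation. The tables list 43309 gene identifiers, of which 42425 have a symbol in the reference table. Where identifiers shared a symbol the one with the highest mean was kept, which left 42405 symbols, and 0 mitochondrially encoded genes are listed. Genes without a symbol hold 0.254% of TPM in SVZ cells and 0.191% in astrocytes. Positions are those of GENCODE on GRCm38.

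Columns sum to between 999576 and 1000000 except in 5 SVZ cells of the ogp series, replicates 4 to 8, whose listed genes sum to between 66189 and 309864 TPM. What is missing from these columns is not stated. Each cell was rescaled to a sum of 1000000 TPM. TPM keeps no read counts, so depth is unknown, no depth-based limit can be given, and cells could not be thinned to a common depth. No columns were identical, and the highest correlation across genes of any SVZ pair was 0.799.

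The plan foresaw summed counts scaled to a common total and, for normalized values, the mean over cells. The mean TPM over cells was therefore used, and 1 TPM replaced 1 count as the limit of detection. The value per gene is log2 of (mean TPM + 1) in the first group over that in the second. Genes with at least 10 TPM in either group enter the list medians. A cell needed 1000 genes at 1 TPM or more, and 0 cells fell below that. No animal is named and cells were pooled, so cells are not replicates and no test, p-value or standard error was computed. Shares of cells carry exact Clopper-Pearson 95% intervals (scipy 1.17.1), which cover counting error only, and a share of 0 has its upper bound from the same interval. For classes with 0 cells the share that 3 counts would make is given as well.

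SVZ cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 on log2(TPM + 1) of the 2000 most variable genes, after leaving out the 15 held out lists, with 10 principal components, 15 neighbours and resolution 1. Genes were not scaled to unit variance. A cluster took the class whose markers had the highest mean log2 difference from the other SVZ cells, if above 1 and with at least 3 markers in 50% of its cells. Without such a class it was called quiescent-like when 3 quiescent markers met that share. Each list median was placed among 10000 random lists of the same size, whose members were drawn from the 50 genes above and below in mean TPM over the cells compared. The percentile is a description and not a test.

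Genes, lists, markers, comparisons and most alternatives were fixed before the data were examined. For astrocytes against SVZ cells, single genes needed 50 TPM in the higher group, detection in 50% of its cells (30% for SVZ), and a ratio of at least 4 in the same direction for striatum, for cortex and against each SVZ series, and up to 12 per direction were named. For striatum against cortex 8 per direction were named. Up to 3 or 4 members per list, with at least 20 TPM, were eligible by the size of their ratio, and Sfrp5, Mki67, Cdkn1a and Cdkn1b were set in advance. Which of the eligible list members are printed was chosen after their values were seen. Predicted genes and pseudogenes were counted but not named. Leading genes of clusters were also chosen after they were seen.

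Several choices were made after the data were examined. These are the rescaling to 1000000, the lack of scaling to unit variance, the naming rule for clusters, the separate look at cluster 3, which lists are treated as the main answers, and the limit of 1.5-fold beyond which a list median is called moved. The matching of random lists was changed after the percentiles had been seen. Matching on the average of the group means had given unchanged simulated lists a median percentile of 14.6, with 15 of 100 draws outside 2.5 to 97.5. Matching on the mean over all cells gave 47.4, with 1 of 100 draws outside. For striatum against SVZ cells the earlier matching had put immediate early genes at percentile 3.72 and oxidative phosphorylation at 94.0. For activated-like against quiescent-like cells it had put oxidative phosphorylation at 36.9 and glycolysis at 2.86. For striatum against quiescent-like cells it had put the Wnt pathway at 16.3 and oxidative phosphorylation at 96.9. For striatum against cortex it had put ventral patterning at 93.1, lysosome at 99.4 and BMP and Id at 98.4, the last 2 now at 94.6 and 92.0.

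The procedure was tested on simulated data with 13 cells against 133. Changes of 2, 4 and 8-fold put into 200 genes came back as log2 medians of 0.99, 1.97 and 2.96, with the right direction in 92.9%, 98.8% and 99.2% of cases. Of 20 cells planted among shuffled cells, 20 were recovered with 0 others. The changed genes and the unchanged lists came from genes with at least 50 TPM in SVZ cells, so genes between 10 and 50 TPM were not covered. Comparisons with the 4 cortex cells were not simulated. The planted cells had 300 genes raised over a background without other structure, which is easier than real states. Alternatives covered totals, filters, pseudocounts, cell sets, series, tissue and clustering. The 18 population libraries (neural stem cells, endothelium, microglia and neuroblasts at 2 to 19 months) have no columns, so the comparison by age was not run.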

Results

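RNA of 150 single cells from the brains of old male C57BL/6 mice was sequenced by Smart-seq2, a method that reads whole transcripts from 1 cell at a time. The subventricular zone (SVZ), the layer beside the lateral ventricle that holds neural stem cells, gave 68 cells of a series named ogp in the column names and 65 of a series named ogp2, sorted as GLAST and CD133 positive, CD45 and O4 negative. Astrocytes, sorted as GLAST positive and CD45 and O4 negative, came from striatum (13 cells) and somatosensory cortex (4 cells). The labels give 23 months for SVZ cells, while their protocol gives 22, and 25 months for astrocytes. Cells from 3 or 4 pooled mice were picked by hand and no animal is named, so each group counts as 1 sample. There are no replicates, no difference was tested, and every SD is a spread between cells. Values are TPM, a unit that makes the transcripts of each cell sum to 1000000, so the read depth per cell is unknown. The median cell had 3479 genes at 1 TPM or more in SVZ (range 1937 to 7986), 3636 in striatum (2860 to 3944) and 3387.5 in cortex (3033 to 3766). The 18 libraries of sorted populations at several ages have no values in the files and were not analysed here.

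The transcripts behind the sort gates were as follows in the 3 groups. Slc1a3, which encodes GLAST, was detected in every cell, with means of 3373 TPM (SD 1866) in SVZ, 3317 (SD 1172) in striatum and 3302 (SD 1234) in cortex. Prom1, which encodes CD133, was detected at 1 TPM or more in 14 SVZ cells (10.5%, 95% Clopper-Pearson interval 5.88 to 17.03), in 0 of 13 striatum cells (interval 0 to 24.7) and in 1 of 4 cortex cells. Ptprc, which encodes CD45, and the myeloid gene Itgam reached 1 TPM in none of the 150 cells. Pecam1 of endothelium stayed near the floor, with means of 1.95 TPM in SVZ, 3.96 in striatum and 2.30 in cortex. Ncam1 averaged 251 TPM in SVZ, 445 in striatum and 142 in cortex. Intervals on shares of cells cover counting error only.

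Astrocytes and SVZ cells were compared to ask what sets stem cells of the old brain apart from astrocytes. Astrocytes had lower mean levels of cell cycle, ribosomal protein and interferon response transcripts, and had less of the stem cell genes Thbs4 and Igfbp5. Mean levels of Id1, Id3 and Id4 were higher in striatum, those of Id1 and Id3 in 1 of its 2 series of cells only. Age label, sort gate and deposited table all differ between these groups, so none of these can be separated from cell type. The median of all 9080 genes with at least 10 TPM in striatum or SVZ was -0.26 (log2 of striatum over SVZ), against which list medians should be read.

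Of the gene lists, those of the cell cycle had the largest median differences between striatum and all SVZ cells. All 23 G2 and M phase genes were lower in striatum, with a median log2 difference of -4.98 (percentile 0 among 10000 random lists of matched expression), and 20 of 22 S phase genes were lower, with a median of -2.22 (percentile 0). The G2 and M phase median was -2.03 with pseudocount 10 and -0.71 when logs were averaged over cells, and the S phase median was -1.12 against ogp2 cells alone. Ube2c averaged 173 TPM (SD 729) in SVZ and was detected in 15 SVZ cells, Cdk1 averaged 93.4 TPM in 13 cells, and both were listed at 0 in all 17 astrocytes. Ccnb1 averaged 100.98 TPM in SVZ, in 12 cells, and reached 1 TPM in no astrocyte. Mcm4 (23.1 TPM, 25 SVZ cells) and Mcm3 (20.3 TPM, 15 cells) were listed at 0 in astrocytes. The SD of each cell cycle gene exceeded its mean, since a minority of SVZ cells carried these transcripts.

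Ribosomal protein genes had a median of -0.97 in striatum (82 of 83 lower, percentile 0) and -0.87 in cortex (72 of 83 lower). Rplp0 averaged 166 TPM (SD 236) in striatum, 192 in cortex and 588 (SD 914) in SVZ. Rps27 averaged 5.98 TPM in striatum and 57.2 in SVZ, a log2 difference of -3.06, and Rpl35a averaged 61.6 and 313 TPM. The typical cell differed less, with a median share of TPM of 1.63% in striatum, 2.00% in cortex and 1.83% in all SVZ cells, 20 of which were activated-like cells with a median of 10.0% (below). The interferon response list had a median of -1.55 in striatum (29 of 32 lower, percentile 0). In cortex it was -4.72 (32 of 32 lower, percentile 0), a value that rests on 4 cells and was not set against random sets of that size. The median share of TPM per cell differed less, with 0.0609% in cortex, 0.116% in striatum and 0.206% in SVZ. The striatum median was -2.53 with cells of the OGStr series only, -0.69 when logs were averaged over cells and -0.79 among genes with 10 TPM in both groups. Bst2 (58.3 TPM, 21 SVZ cells), Oasl2 (41.3 TPM, 17 cells) and Isg15 (31.8 TPM, 6 cells) were listed at 0 in all astrocytes. Immediate early and stress genes had a median of -0.99 (14 of 18 lower, percentile 0.18), with Ier2 at 41.9 TPM in SVZ and listed at 0 in astrocytes. That median was -1.64 against ogp cells but -0.24 against ogp2 cells (percentile 22.5), within the range of random lists.

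The SVZ stem cell list as a whole was lower in striatum by a median of -0.54, which lay at percentile 12.9 and so within the range of random lists. Thbs4 averaged 80.4 TPM (SD 204) in SVZ, in 38 cells, and was listed at 0 in astrocytes. Vim, of the reactive astrocyte list, averaged 135 TPM in SVZ, 0.429 in striatum and 20.1 in cortex, although that list had a median of 0.20. Fabp7 averaged 579 TPM in SVZ and 51.4 in striatum within a fatty acid metabolism list at -0.12. Meis2 averaged 69.4 TPM in SVZ and 20.8 in striatum.

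Mature astrocyte genes had a median of 0.01 in striatum, with 16 of 32 higher (percentile 97.49). Gjb6 was higher in striatum (1689 TPM, SD 780) than in SVZ (615 TPM, SD 741), while Kcnj10 (9.32 and 34.5 TPM) and Mfge8 (2181 and 4776 TPM) were lower. Id3 averaged 2650 TPM (SD 2103) in striatum and 484 (SD 712) in SVZ, Id4 737 and 229 TPM, and Id1 629 and 78.7 TPM. Striatum holds 2 series by its column names, OGStr (11 cells) and OStr (2 cells). Id3 averaged 3089 TPM in OGStr and 238 in OStr, Id4 825 and 250 TPM, and Id1 744 and 0 TPM, so in OStr Id1 and Id3 were below the SVZ mean and Id4 was near it. In cortex Id1 was lower than in SVZ (33.9 TPM), and the BMP and Id list had a striatum median of 0.05. Oxidative phosphorylation genes had a median of 0.00 (46 of 92 higher), which lay at percentile 99.9 because random lists were lower, and whose sign changed under several settings. The other lists lay within the central 95% of random lists. Their medians were -0.31 for Wnt pathway, -0.06 for glycolysis, -0.09 for lysosome, -0.24 for proteasome, -0.61 for Notch pathway and -0.17 for cyclin-dependent kinase inhibitors and p53. Dorsal and ventral patterning genes had medians of -0.53 and -0.13, and the sort markers -0.02. The glycolysis, lysosome and sort marker medians changed sign when group means were scaled by their median ratio.

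A rule set before the data were examined named single genes that differed at least 4-fold in striatum, in cortex and against each SVZ series. It found 34 genes lower in astrocytes and 1 predicted gene higher, among 9080 with at least 10 TPM in striatum or SVZ. The rule was stricter for higher genes, which needed 50 TPM and detection in 50% of cells in both striatum and cortex. Lower genes needed 50 TPM and detection in 30% of SVZ cells, so the 2 counts cannot be compared. The genes listed at 0 in every astrocyte were Selenoh (177 TPM in SVZ, 43 cells), Jpt1 (170 TPM, 40 cells), Apex1 (107.2 TPM, 41 cells), H2afx (75.6 TPM, 41 cells) and Naa35 (58.04 TPM, 50 cells). Pigk, Igfbp5, Slbp, Fuz and Nmrk1 averaged 57.998, 57.3, 75.97, 81.2 and 53.4 TPM in SVZ, against 0.254, 0.954, 1.62, 3.64 and 2.08 TPM in striatum. The insulin-like growth factor binding gene Igfbp5 (ENSMUSG00000026185, GRCm38 chromosome 1, 72857932 to 72874884) was detected in 77 SVZ cells (57.9%, interval 49.03 to 66.4) and in 2 of 13 striatum cells (15.4%, interval 1.9 to 45.4). The 7SL RNA genes Rn7s1 (ENSMUSG00000099021, chromosome 12, 69159295 to 69159594) and Rn7s2 (ENSMUSG00000099250, chromosome 12, 69361182 to 69361481) had the same value in every group, 3143 TPM in SVZ, 23.4 in striatum and 28.6 in cortex. The log2 difference of Rn7s1 was -7.01, and its median differed between SVZ series, with 953 TPM in ogp and 3871 TPM in ogp2.

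**Figure D1:**
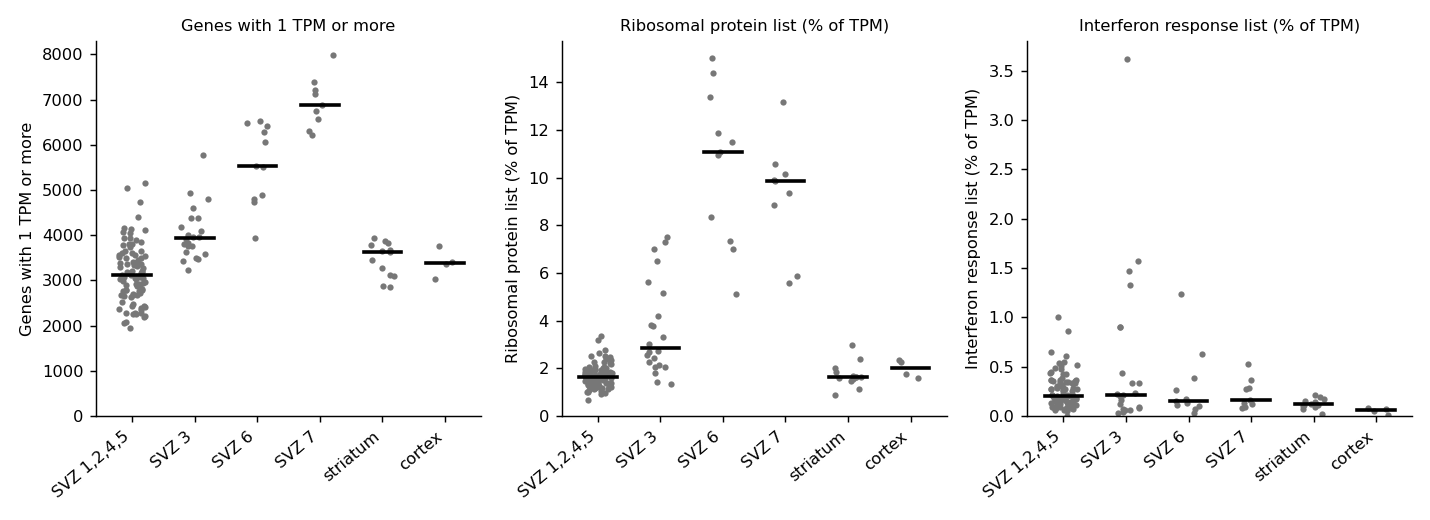
Each point is 1 cell and each bar a median, for SVZ clusters and astrocytes of striatum and cortex; the vertical axes show the number of genes at 1 TPM or more, the ribosomal protein list and the interferon response list (both % of TPM). Clusters 6 and 7 had the most genes and ribosomal protein transcripts, and the interferon share had a median of 0.206% in all SVZ cells, 0.116% in striatum and 0.0609% in cortex.

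Striatum and cortex astrocytes were compared because the label for old astrocytes covers both regions. Cortex astrocytes had more of the dorsal patterning genes Emx2, Lhx2 and Chrdl1, and striatum astrocytes had more of the ventral gene Crym. Mean interferon response levels were higher in striatum, by an amount that depended on the setting and rests on 4 cortex cells. Glycolysis genes were higher in cortex. A gene detected in 0 of 4 cortex cells has an interval of 0 to 60.2%.

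All 4 dorsal patterning genes measured were lower in striatum, with a median log2 difference of -3.12 (percentile 0.01). Emx2 (ENSMUSG00000043969, chromosome 19, 59458372 to 59465357) averaged 8.10 TPM (SD 20.5) in striatum, in 5 of 13 cells, and 108.5 TPM (SD 122.3) in cortex, in 4 of 4 cells, a log2 difference of -3.59. Lhx2 (ENSMUSG00000000247, chromosome 2, 38339281 to 38369733) averaged 30.9 TPM (SD 36.7) and 233 TPM (SD 187). Chrdl1, which is also on the BMP list, averaged 29.9 TPM (SD 50.3) in striatum and 315 TPM (SD 207) in cortex, and Pax6 22.7 and 68.3 TPM. Leaving out each cortex cell in turn gave list medians from -3.51 to -2.79. Of 6 ventral patterning genes 5 were higher in striatum, with a median of 4.57 (percentile 100; range 1.71 to 7.84 over the alternatives). Crym (ENSMUSG00000030905, chromosome 7, 120186380 to 120202111) averaged 1686 TPM (SD 1783) in striatum, in 8 of 13 cells (61.5%, interval 31.6 to 86.1), and was listed at 0 in the 4 cortex cells.

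The interferon response list had a median of 4.18 (13 of 15 higher in striatum, percentile 99.95). It was 1.32 with 10 TPM in both groups, 1.44 with pseudocount 10 and 0.69 by mean logs. The value rests on 4 cortex cells and was not set against random sets of that size. The median share of TPM per cell differed less, with 0.116% in striatum and 0.0609% in cortex. Ifitm3 averaged 160 TPM in striatum but came from 2 of 13 cells, Psmb8 averaged 45.8 TPM in 3 cells, and both were listed at 0 in cortex. Tapbp averaged 53.6 TPM in striatum, in 7 of 13 cells, and 0.285 TPM in cortex. The glycolysis list had a median of -0.71 (12 of 15 lower in striatum, percentile 0.32), with Pgk1 at 152 TPM (SD 152) in striatum and 581 (SD 413) in cortex and Ldha at 228 and 786 TPM. Among genes above 10 TPM in both groups the median log2 difference was -0.40, so part of the glycolysis difference was shared by most genes. After scaling that shift away, glycolysis stood at -0.32 and dorsal patterning at -2.73.

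Other groups of genes lay within the central 95% of random lists. Lysosome genes had a median of 0.36 with Atp6v1a at 71.8 TPM in striatum and 0.0600 in cortex, reactive astrocyte genes 2.54 with C4b at 193 TPM in striatum and listed at 0 in cortex, and BMP and Id genes 1.19 with Id1 at 629 and 33.9 TPM. Notch pathway genes had a median of 1.39 with Hey2 at 34.9 TPM in striatum and listed at 0 in cortex. Medians were 3.47 for immediate early genes, 3.71 for S phase genes, and 0.58 for kinase inhibitors and p53 genes. For immediate early genes the share of TPM per cell went the other way, with medians of 0.098% in striatum and 0.207% in cortex. Fatty acid metabolism genes had a median of -0.50. SVZ stem cell genes stood at 0.08 and sort markers at 0.01. Medians of -0.19 for ribosomal proteins, -0.09 for Wnt pathway, -0.10 for oxidative phosphorylation, -0.04 for proteasome, -0.22 for mature astrocyte genes and -0.20 for 2 G2 and M phase genes changed sign after median-ratio scaling. Slc25a18 (57.1 TPM in striatum, 949 in cortex) and Fzd2 (96.4 and 1.43 TPM) were mature astrocyte and Wnt genes with large differences.

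By the rule for single genes, 216 genes were at least 4-fold higher in striatum and 443 at least 4-fold lower. These were among 8276 genes with at least 10 TPM in either region. The 2 counts cannot be compared. For lower genes detection in 2 of 4 cortex cells was enough, and a mean over 4 cells is less stable than one over 13. Genes above 10 TPM in both groups also had a median log2 difference of -0.40, a shift towards cortex. Besides Crym, the highest in striatum were Slc37a4 (566 TPM), Gstk1 (449 TPM), Csnk2b (246 TPM), Ndufa9 (242 TPM), Gde1 (234 TPM), Cgrrf1 (220 TPM) and Gdf10 (212 TPM), all listed at 0 in the 4 cortex cells. Igfbp2 (ENSMUSG00000039323, chromosome 1, 72824503 to 72852474) averaged 964 TPM (SD 594) in cortex, in 4 of 4 cells, and was listed at 0 in striatum. Tada1, Slc50a1, Praf2, Men1 and Mvk averaged 205, 176, 175, 150.3 and 150.1 TPM in cortex and were listed at 0 in striatum, and Hmgb3 and Zfp330 averaged 138 and 148 TPM in cortex against 0.0415 and 0.123 in striatum. Tada1, Slc50a1, Praf2, Hmgb3 and Zfp330 were each detected in 2 of 4 cortex cells.

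SVZ cells were clustered without the genes of 15 lists, cell cycle and ribosomal protein genes among them, to see which states the sort had captured. Most cells carried quiescent stem cell or astrocyte markers, and a minority carried markers of activated stem cells or transit amplifying cells. The clustering found 7 clusters. Clusters 1 to 5 (28, 26, 22, 21 and 16 cells) met the rule for quiescent-like, with 19 to 21 of 21 quiescent markers in at least 50% of their cells. Clusters 6 and 7 also had 17 and 18 of these 21 markers in that share of cells, so the count alone does not separate the classes. Clusters 6 and 7 (11 and 9 cells) met the rule for activated-like, with 12 and 14 of 16 activated markers. Cluster 7 also met the limits for neuroblasts (mean log2 difference 1.26, 4 of 19 markers), but took the class with the larger difference (2.94). Cluster 3 had a mean log2 difference of -0.76 for quiescent markers and of 2.10 for oligodendrocyte lineage markers, of which 1 of 15 was in 50% of its cells. Quiescent-like cells made up 84.96% of SVZ cells (interval 77.7 to 90.6; 52 cells of ogp and 61 of ogp2) and the 20 activated-like cells 15.04% (interval 9.43 to 22.3). In the pooled clustering 16 of 68 ogp cells were activated-like (23.5%, interval 14.1 to 35.4) and 4 of 65 ogp2 cells (6.15%, interval 1.70 to 15.01). Clustered separately, the series stood at 26.5% (interval 16.5 to 38.6) and 13.8% (interval 6.53 to 24.66), intervals that overlap. No Leiden cluster was named for neuroblasts, ependymal cells, oligodendrocyte lineage, microglia, endothelium, mural cells, neurons or choroid plexus (0 cells each, interval 0 to 2.74, while 3 counts would be 2.26%). Ward clustering put 2 cells of cluster 3 in the oligodendrocyte lineage.

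Cluster 7 was led by mitotic genes. Ube2c averaged 2529 TPM in cluster 7 and 2.33 in other SVZ cells, and Cdk1 1368 and 0.849 TPM. Cluster 6 was led by Rab3b (110.7 TPM, against 1.73 in other SVZ cells) and Mfng (72.6 and 2.09 TPM). Cluster 3 was led by Gfap (601 and 62.5 TPM), with Vim (470 and 67.9 TPM) and Pax6 (105.2 and 19.3 TPM) also among its first 10 genes. The median activated-like cell had 6359 genes at 1 TPM or more and the median quiescent-like cell 3325. The share of activated-like cells depended on the clustering settings, from 15.04% to 31.6% with both series clustered together. It was 13.8% among ogp2 cells clustered alone.

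**Figure D2:**
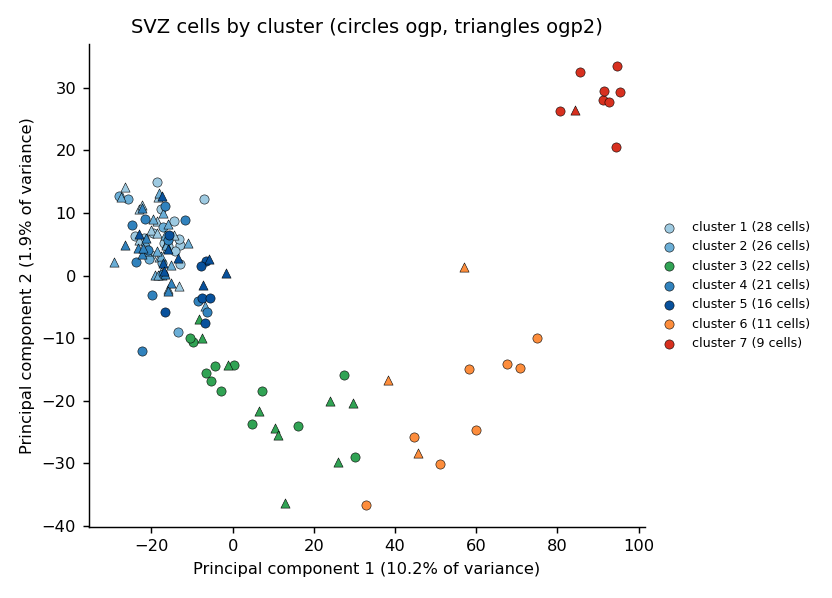
Each point is 1 SVZ cell, placed by principal components 1 and 2 of log2(TPM + 1) (axes give arbitrary units and the share of variance, 10.2% and 1.9%), coloured by cluster, with circles for ogp and triangles for ogp2. Clusters 1, 2, 4 and 5 overlap, cluster 3 lies between them and cluster 6, and the 9 cells of cluster 7 lie apart.

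Activated-like and quiescent-like cells were compared on lists whose genes took no part in the clustering. Genes that vary along with them stayed eligible, and Spc25, Pimreg and Prc1, which are mitotic genes on no held out list, were among the first 10 genes of cluster 7. The cell cycle difference is therefore not independent of how the classes were formed. Activated-like cells had more cell cycle, ribosomal protein, proteasome and immediate early transcripts, and more of the cell cycle inhibitors Cdkn1a and Cdkn2c. Quiescent-like cells had more lysosome and fatty acid metabolism transcripts, and more of the secreted Wnt inhibitor Sfrp5. In the main clustering they also had more reactive astrocyte transcripts, although Vim of that list was higher in activated-like cells. The directions of the reactive astrocyte and interferon response lists depended on the setting. The median over 9359 genes was 0.19, and a shift of 0.20 was shared by genes above 10 TPM in both classes.

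All 26 G2 and M phase genes were higher in activated-like cells, with a median log2 difference of 6.73, and all 26 S phase genes, with a median of 3.50 (both percentile 100). Cdk1 (ENSMUSG00000019942, chromosome 10, 69335146 to 69352938) averaged 621 TPM (SD 835) in activated-like cells, in 10 of 20 (50.0%, interval 27.2 to 72.8), and 0.0438 TPM in quiescent-like cells. Ube2c averaged 1152 and 0.0735 TPM and Ccnb1 671 and 0.0630 TPM. Mki67 was detected in 11 of 20 activated-like and 0 quiescent-like cells. Rrm2 averaged 372 and 2.41 TPM, Uhrf1 105.5 and 0.0641 TPM, and Mcm2 110.9 and 0.245 TPM.

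All 83 ribosomal protein genes were higher in activated-like cells, with a median of 2.23 (percentile 100), and their share of TPM had a median of 10.0% per activated-like cell (range 5.14 to 15.01) and 1.74% per quiescent-like cell (range 0.659 to 7.50). Rplp0 (ENSMUSG00000067274, chromosome 5, 115559467 to 115563727) averaged 2405 TPM (SD 686) and 266 TPM (SD 459), Rpsa 984 and 140.0 TPM, and Rps2 1972 and 283 TPM. Proteasome genes had a median of 0.83 (33 of 35 higher, percentile 100), with Psmd3 at 205 and 59.5 TPM and Psmd2 at 237 and 73.8 TPM. Oxidative phosphorylation genes had a median of 0.34 (70 of 91 higher, percentile 99.2), with Atp5e at 852 and 282 TPM.

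Immediate early and stress genes had a median of 2.54 (16 of 18 higher, percentile 100), with Egr1 at 1229 and 38.3 TPM and Ier2 at 257 and 3.91 TPM. Kinase inhibitors and p53 genes had a median of 1.15 (10 of 11 higher, percentile 99.2). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) averaged 105.8 TPM in activated-like cells, in 12 of 20, and 2.88 TPM in quiescent-like cells, in 1 cell (0.885%). Trp53 averaged 265 and 40.2 TPM, Cdkn2c 116.98 and 20.3 TPM, and Cdkn1b 36.9 and 18.4 TPM. The Notch list had a median of -0.23, although the ligand genes Dll1 (104.3 and 1.66 TPM) and Dll3 (69.7 and 0.712 TPM) were higher in activated-like cells. Dll3 was not higher among ogp2 cells, of which only 4 were activated-like. Mfng averaged 52.7 TPM in activated-like cells and was listed at 0 in quiescent-like cells.

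Lysosome genes had a median of -1.55 (28 of 29 lower in activated-like cells, percentile 0). Cd81 averaged 665 TPM (SD 559) in activated-like and 5002 (SD 2060) in quiescent-like cells, Ctsb 87.9 and 504 TPM, and Npc1 12.3 and 68.5 TPM. The fatty acid metabolism list had a median of -1.14 (22 of 26 lower, percentile 0.7), with Acsl3 at 134 and 1132 TPM, Acsl6 at 100.3 and 796 TPM and Acsbg1 at 130 and 967 TPM. Glycolysis genes had a median of -0.80 (percentile 21.6), with Pfkp at 2.20 and 130.8 TPM and Slc2a1 at 37.2 and 230.0 TPM. BMP and Id genes had a median of -1.13 (8 of 12 lower, percentile 2.16; -0.00648 by mean logs), with Id2 at 98.6 and 1480 TPM and Id3 at 84.1 and 554 TPM.

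The reactive astrocyte list had a median of -2.69 (6 of 7 lower, percentile 0.12), with C4b at 9.53 and 255 TPM and Gfap at 3.23 and 178 TPM. At Leiden resolution 0.5, where all 22 cells of cluster 3 joined the activated-like class, that median was 1.58. The Wnt pathway list had a median of -0.69 (percentile 0.76), which was 0.42 among ogp2 cells alone, with only 4 activated-like cells. Sfrp5 (ENSMUSG00000018822, chromosome 19, 42197971 to 42202252) averaged 2.00 TPM in activated-like cells, in 1 of 20 (5.0%, interval 0.1 to 24.9), and 59.1 TPM in quiescent-like cells, in 32 cells (28.3%, interval 20.2 to 37.6). Fzd2 averaged 6.54 and 56.2 TPM. The interferon list had a median of -0.10 (15 of 32 higher, percentile 31.96) and ranged from -1.07 with ogp cells alone to 1.48 at resolution 0.5. Within it Lgals3bp averaged 62.4 and 301 TPM.

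**Figure D3:**
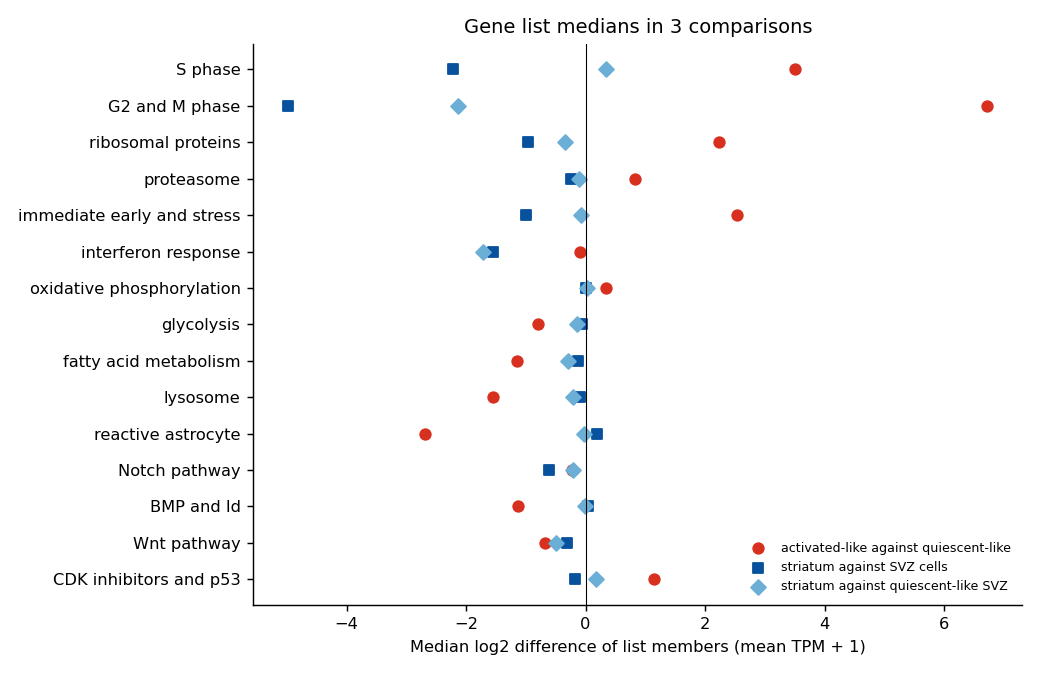
Each point is the median log2 difference over the members of 1 gene list (horizontal axis, log2 of mean TPM + 1) for activated-like against quiescent-like SVZ cells, striatum against all SVZ cells and striatum against quiescent-like SVZ cells. The ribosomal protein median was 2.23 in the first, -0.97 in the second and -0.35 in the last, while the interferon medians were -0.10, -1.55 and -1.71.

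Striatum astrocytes were set beside quiescent-like SVZ cells, the SVZ cells nearest to them in markers. Mean interferon response levels stayed lower in astrocytes, while the ribosomal protein difference was smaller than against all SVZ cells. The means of Thbs4, Igfbp5 and Vim stayed lower in astrocytes, and those of Cdkn1a, Id1 and Id3 were higher in striatum. For Id1 and Id3 this held in the OGStr series only. Cluster 3 raised the quiescent-like means of Thbs4, Igfbp5 and Vim, with 203.8, 165.2 and 470.4 TPM. In clusters 1, 2, 4 and 5 the means were 64.7, 27.98 and 36.8 TPM, still above those of striatum. The genes were detected in 18.7%, 43.96% and 16.5% of cells of these clusters. In striatum the shares were 0%, 15.4% and 7.69%, and the intervals overlapped. The median over 8861 genes was -0.19.

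The interferon response list had a median of -1.71 in striatum (27 of 32 lower, percentile 0) and -4.65 in cortex (31 of 31 lower). The cortex value rests on 4 cells. Per cell, the median share of TPM was 0.0609% in cortex and 0.208% in quiescent-like cells. The striatum median was -0.84 with 10 TPM in both groups and -0.55 by mean logs. Bst2, Oasl2, Isg15 and Gbp3 averaged 50.0, 40.8, 35.7 and 37.1 TPM in quiescent-like cells, in 15, 11, 5 and 7 cells, and were listed at 0 in astrocytes. Ribosomal protein genes had a median of -0.35 (67 of 83 lower, percentile 1.27), which was 0.0182 when logs were averaged over cells. Their share of TPM averaged 1.55% in OGStr and 2.69% in the 2 OStr cells, against 2.07% in quiescent-like cells, so the lower level was that of OGStr. Rps27 averaged 5.98 TPM in striatum and 38.99 in quiescent-like cells, and Rpl35a 61.6 and 194 TPM. The SVZ stem cell list had a median of -0.49 (14 of 20 lower, percentile 14.5). Within it Thbs4 (ENSMUSG00000021702, chromosome 13, 92751590 to 92794818) averaged 91.8 TPM (SD 219) in quiescent-like cells, in 31 cells (27.4%, interval 19.5 to 36.6), and was listed at 0 in all 13 striatum cells (interval 0 to 24.7). Igfbp5 averaged 0.954 and 54.7 TPM and Meis2 20.8 and 63.9 TPM. Egfr averaged 6.38 TPM in striatum, 52.2 in cortex, from 1 of 4 cells, and 31.1 in quiescent-like cells.

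Cdkn1a averaged 106.1 TPM (SD 160) in striatum, in 6 of 13 cells (46.2%, interval 19.2 to 74.9), and 2.88 TPM in quiescent-like cells, in 1 cell (0.885%, interval 0.0224 to 4.83), within a list whose median was 0.18. Id3 averaged 2650 and 554 TPM and Id1 629 and 73.8 TPM, within a BMP and Id list at -0.01. In the 2 OStr cells the means of Id3 and Id1 (238 and 0 TPM) were below those of quiescent-like cells. In cortex Id1 was lower than in quiescent-like cells. Wnt pathway genes had a median of -0.50 (percentile 1.87), which was 0.15 against ogp cells alone. Sfrp5 averaged 4.70 TPM in striatum, and Ctnnb1 0.828 TPM in striatum, 65.4 in cortex and 55.7 in quiescent-like cells. Vim averaged 0.429 and 121.2 TPM and S100a6 110 and 293 TPM, in a reactive astrocyte list at -0.03. S100a6 averaged 751 TPM in cluster 3 and 182 in clusters 1, 2, 4 and 5. It was detected in 60.4% of cells of these 4 clusters and in 61.5% of striatum cells.

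Mature astrocyte genes had a median of -0.20 (percentile 47.97), with Gjb6 at 1689 TPM in striatum and 718 in quiescent-like cells and Kcnj10 at 9.32 and 38.45 TPM. Slbp of the S phase list averaged 1.62 and 50.6 TPM, although 8 of the 14 S phase genes measured were higher in striatum (median 0.34), and 3 G2 and M phase genes had a median of -2.14. Hexa averaged 35.9 and 176 TPM in a lysosome list at -0.21. Oxidative phosphorylation genes had a median of 0.03 (percentile 99.9). Medians were -0.29 for fatty acid metabolism, -0.14 for glycolysis, -0.12 for proteasome, -0.07 for immediate early, -0.22 for Notch, -0.57 for dorsal patterning, 0.52 for ventral patterning and -0.21 for sort markers, all within the central 95% of random lists. The BMP and Id and reactive astrocyte medians changed sign after median-ratio scaling.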

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

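Of the tests here, those on activated-like cells as a source of 7SL RNA, on a few SVZ cells with high interferon levels, on striatal astrocytes within the SVZ sort, and on the number of genes detected were chosen after the result was seen. The others had a written prediction before their value was seen.

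Cortex, with 4 cells, is the only group small enough for a comparison of each extreme cell with the rest, and 2 of 21 measures stood out. Cortex replicate 1 had 0.01981% of its TPM in G2 and M phase genes, against 0 to 0.000298% in the other 3 cells. Cortex replicate 3 had 0.01056% of its TPM in ventral patterning genes, against 0 to 0.00104%. Chance picks about 1 in 20 such groups, so 2 of 21 is near what chance gives, and no explanation was tested.

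The 7SL RNA genes Rn7s1 and Rn7s2 were far lower in astrocytes than in SVZ cells. Activated-like cells were not the source, since the log2 difference of striatum from quiescent-like cells alone was -7.10. If library preparation or alignment had differed between the deposited tables, other small noncoding RNAs were predicted to be lower too. Their median was 0.4942, past the bound set in advance against this explanation, but that bound was set aside after the value was seen. The reason was that only 4 genes could be measured and all but Rn7sk averaged under 30 TPM in both groups. Rn7sk was higher in striatum (197 TPM, against 47.3 in SVZ, log2 difference 2.03). The others differed in both directions, from -0.36 to 1.17. Table, age and sort differ along with cell type, and the median also differed within SVZ (953 TPM in ogp, 3871 in ogp2), so a technical source and a difference between the cells cannot be told apart.

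Interferon response genes such as Bst2, Oasl2 and Isg15 were lower in astrocytes. For the summed list share, a few SVZ cells with high levels are not the whole cause. The median SVZ cell had 1.783 times the list share of the median striatum cell. In that share 1 of 13 striatum and 0 of 4 cortex cells lay above the SVZ median. Abundant members weigh most in a summed share, so it cannot decide this for genes detected in few SVZ cells. The list median was -0.69 when logs were averaged over cells. The 2 OStr cells of striatum, with shares of 0.187% and 0.213%, were near the SVZ median of 0.206%, while OGStr cells averaged 0.108%. RNA of microglia, which the CD45 gate would remove, is not the whole cause either, since the median against the 70 SVZ cells with no microglia marker was -1.183. The unequal number of cells may account for part, as random sets of 13 SVZ cells against the other 120 gave a typical median of -0.5347 against the observed -1.55, between the bounds set in advance. A difference of age, tissue or deposited table remains open and untested.

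Clusters 1, 2, 4 and 5 of the SVZ cells were set as a group beside striatum astrocytes. All 13 striatum cells had their highest correlation across genes with 1 of these clusters and 0 with cluster 3, which could reflect astrocytes within the SVZ sort, but so had all 4 cortex cells, and the resemblance is not particular to striatum. The SVZ stem cell list had a median of -0.53 in striatum against clusters 1, 2, 4 and 5 (percentile 8.77), within the range of random lists. Its share of TPM per cell went the other way, with medians of 0.734% in striatum and 0.687% in these clusters. Astrocytes and quiescent stem cells cannot be told apart by these values. In cluster 5 a smaller number of detected genes was not the source of the low ribosomal protein level. Its cells had a median of 4056 genes, against 3932.5 in cluster 3, and the list differed by -1.105. Clusters 1, 2 and 4 had fewer genes (medians of 3198.5, 2938.5 and 2676), and for them this was not tested.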

How the results depend on the processing

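The tests with other pseudocounts, mean logs, 10 TPM in both groups, TPM as deposited, median-ratio scaling, unit variance, or without the 5 low-sum, most-gene or oligodendrocyte-marker cells were chosen after the result was seen. No paired analysis was possible because no label links cells to animals. Not run for lack of counts or columns were TMM, thinning, the deepest cell by total count and every test of the populations, and the mean over cells is the value reported.

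Of the 11 list medians taken as main answers, 196 of 197 values kept their direction, 27 were moved and 1 was reversed. Of values for named genes 2190 of 2198 did, with 385 moved and 6 reversed, and of the other lists 1021 of 1148 did, with 13 reversed and 1014 neither moved nor reversed. Reversed means a change of sign in a list outside the central 95% of random lists or in a gene that differed at least 4-fold. The other changes of sign were in lists within that range and genes that differed less. These counts include settings that could not change a value. With 0 cells below the cell filter, removing it repeated the main result, and limits on TPM left the value of each gene as it was. The ranges were -3.52 to -2.64 for dorsal patterning (striatum against cortex), -1.18 to -0.54 for ribosomal proteins (striatum against SVZ) and -0.76 to -0.01 for the stem cell list (against quiescent-like). Apart from which cells changed class, the cause of the values below was not tested.

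Activated-like cells made up 31.6% at Leiden resolution 0.5, 23.3% with 20 principal components, 26.5% with ogp and 13.8% with ogp2 cells clustered alone, and 28.9% without the 5 low-sum cells. In the pooled clustering ogp had 23.5% and ogp2 6.15%. At resolution 0.5, activated against quiescent medians were 5.59 for G2 and M, -0.86 for lysosome and 1.58 for reactive astrocyte genes, with Gfap at 2.05.

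With only ogp cells, G2 and M stood at -5.67 (striatum against SVZ) and Wnt at 0.15 (against quiescent-like). With only ogp2 cells, G2 and M stood at -3.85 and, activated against quiescent, 5.66, with Wnt at 0.42 and Dll3 at -0.71. The activated against quiescent values of ogp2 rest on 4 activated-like cells. With cortex in place of striatum, interferon stood at -4.72 and -4.65, Id1 at -1.19 and -1.10 (against SVZ and quiescent-like), and against quiescent-like Egfr at 0.73 and Ctnnb1 at 0.23. With OGStr cells only, interferon stood at -2.53.

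Interferon in striatum against cortex was 3.39 with no minimum, 1.496 at 50 TPM, 1.32 at 10 TPM in both groups, 7.24 and 1.44 with pseudocounts 0.1 and 10, and 0.69 by mean logs. Without each cortex cell it was 4.18 to 4.58. G2 and M against SVZ was -5.96 at 50 TPM, -8.11 and -2.03 with pseudocounts 0.1 and 10, and -0.71 by mean logs. Activated against quiescent it was 9.10, 4.26, 4.31 by mean logs and 3.84 at 10 TPM in both. The pseudocount acts by construction where a group is near 0.

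By mean logs, interferon was -0.69 (against SVZ) and -0.55 (against quiescent-like), ribosomal proteins 4.51 (activated) and 0.0182 (against quiescent-like), and Wnt 0.40 (activated). With 10 TPM in both groups, interferon was -0.79 and -0.84. Oxidative phosphorylation, near 0, changed sign. Against SVZ it was -0.0239 without ribosomal totals, -0.0411 with no minimum, -0.0337 for OGStr, -0.0119 without low-sum cells and -0.00262 without the cells with most genes. Against quiescent-like it was -0.00799 with no minimum, -0.00549 for ogp2, -0.00103 without low-sum cells and -0.00560 without the cells with most genes.

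Depth is unknown, so a value of 0 cannot be told from a transcript that was missed.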

Other observations

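All comparisons here were chosen after the result was seen, and none was planned.

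Cluster 3 (22 cells) differed from the other quiescent-like cells in the genes that had been left out of the clustering. Ribosomal protein genes had a median log2 difference of 1.09 (80 of 83 higher), interferon response genes 1.99 (30 of 34), immediate early genes 1.55 (13 of 16) and reactive astrocyte genes 2.64 (9 of 10), while lysosome genes had a median of -0.38 (24 of 30 lower). These are differences of means, and the median interferon share per cell was 0.213% in cluster 3 and 0.207% in the other quiescent-like cells, so the typical cell did not differ. Thbs4 was detected in 14 of 22 cells of cluster 3 (63.6%, interval 40.7 to 82.8) and in 17 of 91 cells of clusters 1, 2, 4 and 5 (18.7%, interval 11.3 to 28.2). Igfbp5 was detected in 17 of 22 and 40 of 91 cells, Gfap in 12 of 22 and 18 of 91, Prom1 in 4 of 22 and 2 of 91, and Isg15 in 4 of 22 and 1 of 91. Set against quiescent-like cells without cluster 3, striatum had a ribosomal protein median of -0.07 (percentile 93.99) and an interferon median of -1.26 (percentile 0).

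SVZ replicates 14 and 76, both in cluster 3, each had 7 of 15 oligodendrocyte lineage markers, with 0.777% and 0.675% of their TPM in these genes, while no other SVZ cell had more than 6. Prom1 was detected in 8 of 20 activated-like cells (40.0%, interval 19.1 to 63.9) and in 6 quiescent-like cells (5.3%, interval 2.0 to 11.2).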
